A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

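The series holds 5 microarrays of tag sequences from the yeast deletion collection, in which each strain lacks 1 gene copy and carries short DNA barcodes, the UPTAG and the DNTAG, that identify it. Per the labels, pooled heterozygous strains were grown on agar, genomic DNA was prepared from frozen aliquots, and the UPTAGs and DNTAGs were amplified in separate PCRs of 50 cycles from about 50 ng of DNA in 20 µl, with a Cy3 or Cy5 dye on the labelled primer. Each array received 2 labelled samples. On 3 arrays both channels held Pool A, on 1 array both held Pool B, and on 1 array the Cy3 channel held Pool A and the Cy5 channel held Pool B. No dye-swapped array was analysed here. Nothing in the labels says that the 3 Pool A arrays came from separate cultures or DNA preparations, so p-values measure only the spread between these arrays, which may be technical.

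The deposited values are log2 ratios of the 2 channels, 1 per spot, for 22575 spots with 0 missing values. The log base was settled from the values: raised to the power of 2, 100% of the values with a ratio under 1.5 were numbers with 3 decimals, against 12.1% for base 10 and 9.73% for base e. The scanner, the background treatment and any normalization by the authors are not given in the sources used here. The medians of the named spots were -0.33, 0.07 and 0.03 on the Pool A self-self arrays (replicates 1 to 3), -0.77 on the Pool B self-self array and -0.50 on the Pool A versus Pool B array, so the deposited columns had not been centred on the named spots. The direction of the ratio is not stated. Positive values were taken as Cy5 over Cy3, that is as more signal from Pool B on the mixed array, and this direction is called likely only: the series design describes every differential strain as diluted further in Pool A, and among strains with both tags differing by at least 2 log2 units 14 were positive and 2 negative.

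Spot names came from the platform annotation supplied with the values, which gave 1 gene for 18794 spots and no gene for 3781. These named 5325 genes, matched by gene identifier to a gene table of assembly R64, which was used only for names, chromosomes and gene order. No coordinates are given because the files name no build. The table lacked 4 of the genes and changed 0 symbols. The spots form 2 blocks offset by 10971 spot numbers, with the same gene at the same place of both blocks for all 9397 named spots of a block. These were taken as the 2 tags of each strain and are called the first and the second tag block, because which block holds UPTAGs is not given. For 793 genes, each block holds a run of 5 further spots. Spots of 1 tag were averaged, which gave 10888 tags, of which 9302 rest on 1 spot, 24 on 5 and 1562 on 6. The mean of both tags gave 5444 strains, or more exactly tag sets, since 105 genes have more than 1.

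Each array was centred on the median of its named spots. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) with 3 groups: Pool A self-self (3 arrays), Pool B self-self (1 array) and Pool A versus Pool B (1 array). All residual spread came from the 3 Pool A arrays, and each lone array was assumed to vary like them. Tests were two-sided, and a call is a Benjamini-Hochberg adjusted p under 0.05. The contrasts were the Pool A versus Pool B array minus the Pool A mean (which removes a tag's dye effect only as far as the mixed array shares it), the Pool B self-self array minus the Pool A mean, the Pool A mean against 0, and each Pool A array minus the other 2, with the Pool B array as a separate group in that fit. The mixed array and the 3 Pool A arrays share a date prefix in their titles and the Pool B array does not, so the first contrast lies within 1 batch by date. The number of arrays limits the precision: the median standard error of a strain's difference was 0.20 and that of a tag's was 0.25, in log2 units.

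The groups, the tests, the alternatives, 17 gene lists and the rule for named strains were fixed before the data were examined. The rule took, among called strains with both tags in the direction of the mean, the 20 with the largest difference in the direction of most calls and the 5 with the largest in the other. It also took the 3 strains with both tags called and a difference nearest to the smallest dilution step, and the member of each gene list with the largest difference. Lists and chromosomes were tested with Fisher's exact test on called strains against all strains tested, with each direction alone added later, and the lists also with camera, once with its preset correlation and once with an estimated one. The lists were cytosolic ribosomal proteins, mitochondrial ribosomal proteins, proteasome, tRNA synthetases, RNA polymerase subunits, nuclear pore, cell division cycle genes, RAD genes of DNA repair, SEC genes of secretion, vacuolar sorting and vacuolar ATPase genes, peroxisome, autophagy, amino acid biosynthesis, ergosterol biosynthesis, histones and chromatin silencing, mitochondrial respiration, and open reading frames without a standard name.

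After the data were seen, 2 stretches of chromosome IV were defined from the first tag block alone, as runs of at least 3 strains with a difference of at least 2 and gaps of at most 30 genes. Their strains are described as chosen after their values were seen. The alternatives that subtract a running median along the spots, and that leave out tags resembling the unnamed spots at the end of each block, were also added then.

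The fit was tested on simulated data for the contrast of the mixed array against the Pool A arrays, with 40 strains changed at each step among 5444 strains and 10888 tags. It called 1 strain at a step of 0.33, 39 at 1, and 40 at each of 2, 3 and 5. Of the 80 tags at each step it called 1, 50, 80, 80 and 80. It also called 10 of 10488 unchanged tags and 7 of 5244 unchanged strains. These simulations gave all arrays the same spread, and a simulated lone self-self array gave 0 calls among 10888 tags.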

Results

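Barcode abundance was compared between 2 pools of heterozygous yeast deletion strains on 5 two-colour tag arrays: 3 arrays of Pool A against itself, 1 of Pool B against itself and 1 of Pool A against Pool B. Per the series design, 94 strains were added to the pools in unequal amounts and the other strains in equal amounts. The unequal strains entered Pool B undiluted, at 1:8 or at 1:64, and were diluted further in Pool A by 0.33 to 5 log2 units or were not added to it. Which strains these were, and which step each received, is not given in the labels. The series title sets the purpose as statistics for such arrays. Values below are centred log2 ratios, and a difference is the value on the mixed array minus the mean of the 3 Pool A self-self arrays, with positive differences taken as the likely direction of more signal from Pool B. There was 1 mixed array, so no difference has a repeat of its own, and the standard errors (SE) rest on the spread of the Pool A arrays (median SD of a strain 0.15, n = 3).

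The strains that stood furthest apart between the pools were positive and lay in 2 distant groups of neighbouring genes on chromosome IV. TFB3 (YDR460W), which encodes a subunit of the transcription and DNA repair factor TFIIH, differed by 6.55 ± 0.19 (SE) from a Pool A self-self mean of -0.09 ± 0.10 (SD, n = 3), and by 4.33 ± 0.16 with quantile normalization between arrays. PFA5 (YDR459C), a palmitoyltransferase gene, differed by 4.80 ± 0.20. TOM1 (YDR457W), a ubiquitin ligase gene, differed by 4.59 ± 0.19. THI3 (YDL080C), a regulator of thiamine synthesis genes, differed by 4.25 ± 0.21 and UBX3 (YDL091C) by 4.14 ± 0.20. In these 5 strains both tags were called, and limma's adjusted p ran from 3.28e-19 for TFB3 to 4.48e-14 for THI3. Such p-values for a lone array cannot be taken as calibrated. The same test called 1190 of 5444 strains (21.9%) on the lone Pool B self-self array, whose channels held the same pool. That array has a different title date from the mixed array. No strain was called with a Pool A array in the lone place against the other 2. On the Pool B self-self array the 5 strains above lay between -0.50 (TOM1) and 0.30 (THI3). All 5 were called with each choice of reference arrays that was tried.

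**Figure D1:**
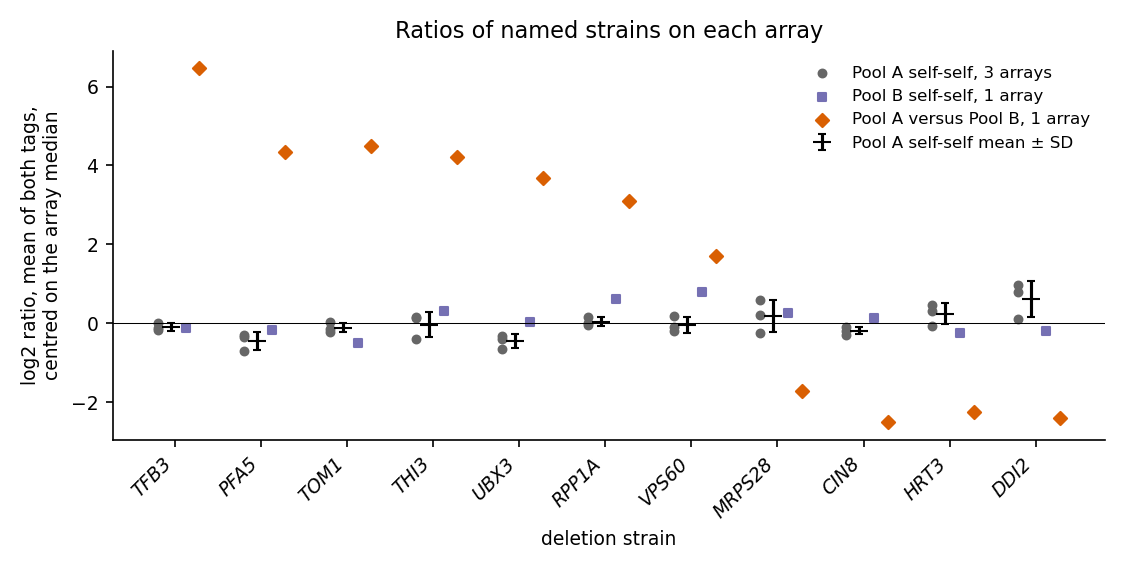
Centred log2 ratios (mean of both tags) of 11 named strains on each array, with grey points for the 3 Pool A self-self arrays, a bar for their mean ± SD, squares for the Pool B self-self array and diamonds for the mixed array. TFB3 reached 6.46 and DDI2 -2.39 on the mixed array, while the self-self values of all 11 strains lay within about 1 log2 unit of 0.

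Over all 5444 strains, limma called 402, of which 84 were positive and 318 negative. Without Pool A replicate 2 the negative strains numbered 132, without centring the counts were 31 and 196, and with quantile normalization they were 105 and 179. Chromosome IV held 100 of the calls among its 707 strains (Fisher's exact test of calls in either direction, adjusted p = 2.37e-10 over 16 chromosomes), and chromosome XI held fewer than the rest, with 8 among 306 (adjusted p = 0.00333), which was lost with both tags required to be called (adjusted p = 0.317) and for negative calls alone (0.0589). Tests of each direction alone were added to the planned test. All of these tests count strains of 1 mixed array as independent, so their p-values measure no spread between repeats. Of the 84 positive strains, 61 were on chromosome IV (adjusted p = 1.83e-35). Against a rest that includes chromosome IV, no other chromosome had more positive calls by this test, and chromosomes XV and XVI had fewer. Chromosome IV raises that rest, so these results say little about the other chromosomes by themselves. Of these 61 positive calls, 51 fell in 2 stretches of neighbouring genes, and the rest of chromosome IV held 10 positive and 39 negative calls. The shorter, from SRP14 (YDL092W) to RPL31A (YDL075W), held 18 strains with 13 positive calls. The longer, from GPI19 (YDR437W) to ITR1 (YDR497C), held 56 strains with 38. Neither held a negative call. The median difference of the 74 strains was 1.08 (quartiles 0.50 and 2.33), against -0.07 for the 5366 strains placed elsewhere. These counts and medians include the first tag block, whose values defined the stretches. In the second tag block alone the medians were 1.25 and -0.05. Of the 23 strains of the stretches that were not called, 19 had a difference above 0 and the highest was 0.62. The Pool B self-self array minus the Pool A mean gave the 74 strains a median of 0.37, against -0.03 elsewhere. A small positive difference therefore need not mark unequal amounts.

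**Figure D2:**
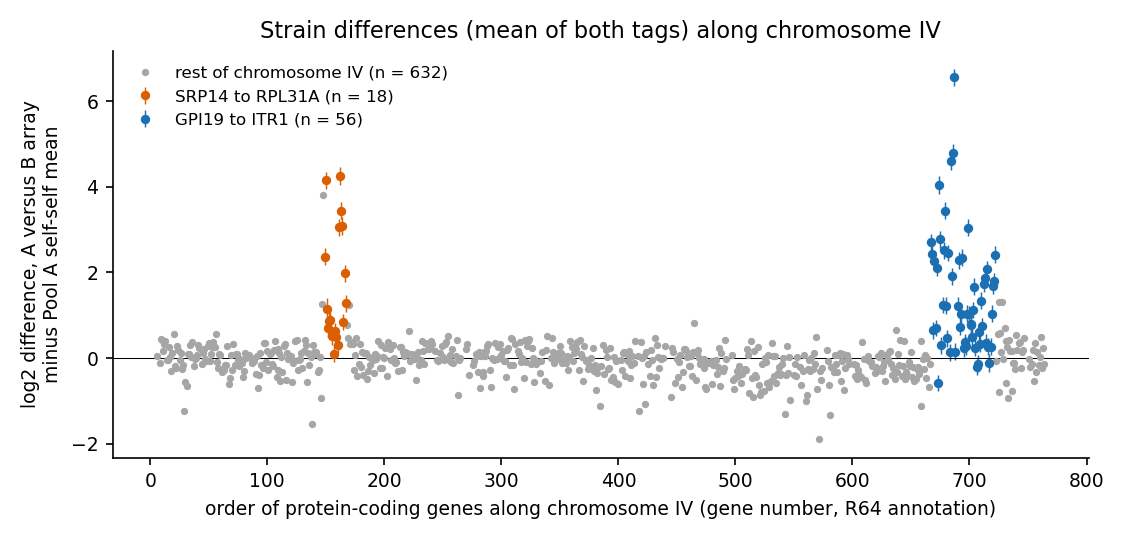
Log2 difference of each chromosome IV strain (mixed array minus Pool A self-self mean, mean of both tags) against the order of protein-coding genes, with SE bars for the strains of the 2 stretches. The medians of the 18 strains from SRP14 to RPL31A (1.01) and the 56 from GPI19 to ITR1 (1.08) lie above that of the rest (-0.04). Some of the 56 lie below 0. The plot leaves out 1 tag set without a place in the gene order.

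The strains named next, and members of gene lists other than the one furthest from 0, were chosen after their values were seen. In the stretches, ECM11 (4.05 ± 0.21), YHP1 (3.44 ± 0.20), MRK1 (3.43 ± 0.20), MDH3 (3.09 ± 0.21), RPP1A (3.05 ± 0.19), TRS31 (3.04 ± 0.20), RPS17B (2.77 ± 0.20) and GPI19 (2.70 ± 0.19) followed the first 5. MDH3 encodes the peroxisomal malate dehydrogenase and TRS31 a subunit of the TRAPP trafficking complexes. The lowest called members were LRS4 (0.65 ± 0.20), NUR1 (0.69 ± 0.20) and APT2 (0.70 ± 0.19). The Pool B self-self array differed from the Pool A mean by 0.82, 0.63 and 0.38 in these strains. Only 6 positive calls outside the stretches reached a difference of 1, and all of these except MAG1 lay on chromosome IV. PMT5 (YDL093W, 3.81 ± 0.20), PMT1 (YDL095W, 1.26 ± 0.19) and YET3 (YDL072C, 1.23 ± 0.19) flank the shorter stretch, and 1 tag set of RPL37B (YDR500C, 1.30 ± 0.20) and LPP1 (YDR503C, 1.31 ± 0.19) follow the longer one. PMT1 and PMT5 encode protein mannosyltransferases. The 2 tags read 1.51 and 6.12 in PMT5, 0.70 and 1.90 in the RPL37B tag set and 2.00 and 0.62 in LPP1. In PMT1 (1.35 and 1.17) and YET3 (1.30 and 1.15) they lay closer together. MAG1 (YER142C, chromosome V), a DNA glycosylase gene, differed by 1.40 ± 0.23 through its first tag (2.57) and not its second (0.23), and its ratio was already 2.79 ± 0.43 (SD, n = 3) on the Pool A self-self arrays. The 23 positive strains on other chromosomes had a median difference of 0.69, against 1.67 for the 61 on chromosome IV.

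The sizes can be set beside the dilution steps of the design. The 84 positive strains need not all have been added in unequal amounts. The same test gave 465 positive strains on the Pool B self-self array, and 22 of the 84 lay below 1 and outside chromosome IV. By the mean of both tags, 1 of the 84 positive strains (TFB3) exceeded 5 log2 units, 11 lay from 3 to 5, 12 from 2 to 3, 23 from 1 to 2 and 37 below 1. By the larger tag, 6 exceeded 5, 13 lay from 3 to 5, 15 from 2 to 3, 28 from 1 to 2 and 22 below 1. With quantile normalization, 0 of 105 positive strains exceeded 5. By the mean of both tags the median was 1.13 and the smallest 0.62, and the smallest negative call was -0.62. The threshold for a call thus lay above the smallest step of 0.33. The absence of calls near that step follows from the threshold. In simulated data, 1 of 40 strains changed by that step was called. The 3 strains with both tags called that came nearest to it were all negative: ECM3 (-0.87 ± 0.19), MIX23 (-0.87 ± 0.20) and GLG2 (-0.88 ± 0.19). With the Pool B self-self array as the reference, MIX23 (0.03) and GLG2 (0.59) turned positive.

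Negative differences were more frequent and smaller. Per the series design no strain was lower in Pool B, so under the direction taken none of these differences was designed. What they reflect was not tested. DDI2 (YNL335W), a DNA damage-inducible cyanamide hydratase gene, differed by -3.01 ± 0.24, and HRT3 (YLR097C), an F-box protein gene, by -2.49 ± 0.21. CIN8 (YEL061C), a kinesin motor gene, differed by -2.31 ± 0.19, through its second tag (-4.15) and not its first (-0.48). MRPS28 (YDR337W), a mitochondrial ribosomal protein gene, differed by -1.90 ± 0.23 and NSE4 (YDL105W), a subunit of an SMC complex, by -1.53 ± 0.21. BUD13 (-1.53 ± 0.22), the autophagy kinase gene ATG1 (-1.38 ± 0.21), the sphingoid base kinase gene LCB4 (-1.36 ± 0.21), PAL1 (-1.33 ± 0.20) and DOT6 (-1.32 ± 0.19) completed the first 10. The next 10 were TFB1, YIL092W, DOC1, UPS3, YDL218W, KAP114, SRL4, RTG3, SME1 and PUS5, from -1.31 for TFB1 to -1.20 for PUS5. TFB1 encodes another TFIIH subunit and lay at 1.49 ± 0.30 (SD, n = 3) on the Pool A self-self arrays, so that its value on the mixed array was 0.17. Of these 20 strains, 11 had both tags called and 6 were on chromosome IV, outside the stretches.

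The negative calls depended on the reference arrays more than the positive ones did. Over all 318, the median was -0.78, 261 were smaller than 1 in size and 30 had both tags called. With all 4 self-self arrays as one reference, 6 negative and 27 positive calls remained. The 6 were DDI2, HRT3, CIN8, MRPS28, NSE4 and PAL1, and 25 of the 27 lay in the stretches, the others being PMT5 and the RPL37B tag set, both named after their values were seen. A lost call need not mean a smaller difference. The differences of BUD13 and ATG1 grew with this reference, since their Pool B self-self values (0.78 and 0.35) lay above their Pool A means. Those of DOT6 and TFB1 shrank, and no named strain changed sign.

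Of the 17 gene lists, 0 passed the planned test of calls in either direction. When positive calls were tested alone, which was not planned, 2 lists held more of them than the rest of the collection. Cytosolic ribosomal proteins had 8 positive and 5 negative calls among 139 strains (Fisher's exact test, adjusted p = 0.891 for calls in either direction and 0.0213 for positive calls), with 8 and 6 when adjusted over the list alone. RPP1A, a ribosomal stalk protein gene, differed by 3.05 ± 0.19, RPS17B by 2.77 ± 0.20, RPS18A by 2.52 ± 0.19, RPL31A by 1.28 ± 0.20 and RPL27B by 1.04 ± 0.19. These 5 lie in the stretches, and the other 3 positive members (RPL30, RPS6B and an RPL37B tag set) do not. Pool B self-self minus the Pool A mean gave the 5, in the order named, 0.56, 0.28, 0.48, 0.68 and 0.99. RPL27B thus differed on that array almost as much as on the mixed one. RPS23B (-1.19) was the most negative member. Vacuolar sorting and vacuolar ATPase genes had 5 positive and 1 negative calls among 64 strains (adjusted p = 0.891 in either direction and 0.0246 for positive calls), and 5 and 1 when adjusted over the list alone. VPS60 (1.74 ± 0.20), VPS3 (1.69 ± 0.20), VPS52 (1.34 ± 0.19) and VPS72 (0.74 ± 0.19) lie in the longer stretch and VPS75 (0.72) does not. Pool B self-self minus the Pool A mean was 0.84 for VPS60, 0.69 for VPS3, 0.08 for VPS52 and 0.36 for VPS72. VPS60, VPS3 and VPS52 encode proteins of endosomal sorting and tethering, while VPS72 encodes a chromatin remodelling subunit. With both tags required to be called, adjusted p in either direction was 1 and 0.585. Both positive-only results ended without centring (adjusted p = 0.432 for each) and with quantile normalization (0.0638 for each), and the vacuolar one also with the blocks centred separately (0.0589) and with arrays scaled to one spread (0.187). As whole sets, neither list was shifted by camera (adjusted p = 0.684 for the ribosomal and 0.884 for the vacuolar list, and adjusted p = 0.997 for both with an estimated correlation). Both lists had a negative median (-0.03 and -0.08) and a positive mean (0.03 and 0.01), and the ribosomal median was 0.06 after quantile normalization.

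The other 15 lists passed neither test in either direction. Mitochondrial respiration had 0 positive and 9 negative calls among 85 strains, led by an ATP11 tag set (-0.81 ± 0.21). Mitochondrial ribosomal proteins had 2 positive (MRPL28 1.22, RSM28 1.04) and 7 negative calls among 68, led by MRPS28. Without centring, with arrays scaled to one spread and with quantile normalization, the negative calls numbered 4, 2 and 2 for respiration, 1, 1 and 2 for mitochondrial ribosomal proteins, 2, 1 and 1 for autophagy genes, 4, 2 and 3 for amino acid biosynthesis, 1, 0 and 1 for tRNA synthetases and 16, 14 and 13 for strains without a standard gene name. Nuclear pore genes had 0 and 4 among 25, led by NUP192 (-0.996 ± 0.208). RNA polymerase subunits had 0 and 3 among 34, led by RPC82 (-0.98 ± 0.20). Peroxisome genes had 0 and 3 among 27, led by PEX18 (-1.19 ± 0.20). Autophagy genes had 0 and 3 among 36, led by ATG1. The proteasome had 0 and 2 among 34, led by an RPN9 tag set (-1.12 ± 0.19), and histones and silencing genes 0 and 2 among 27, led by HST4 (-1.09 ± 0.20). The tRNA synthetases had 0 and 2 among 20, led by ILS1 (-0.74 ± 0.21). Amino acid biosynthesis had 1 and 5 among 95, with MET3 (0.92 ± 0.19), the ATP sulfurylase gene, furthest from 0. Pool B self-self minus the Pool A mean was 0.79 for MET3. CDC23 (-0.76 ± 0.20) was the only call among 40 cell division cycle genes, through its second tag (-1.90) and against its first (0.37). RAD10 (-0.77 ± 0.21) was the only one among 29 RAD genes, and its call was lost with arrays scaled to one spread. SEC genes had 0 calls among 36, with SEC7 at -0.61 ± 0.20 (limma adjusted p = 0.0635), and ergosterol genes 0 among 20, with ERG4 at 0.44 ± 0.19 (limma adjusted p = 0.17). Strains without a standard gene name had 2 and 23 among 355, led by YIL092W (-1.31 ± 0.20). Among the called leaders of these lists, only the second tag was called in the ATP11 tag set, NUP192, RPC82, PEX18, ILS1, CDC23 and RAD10. In HST4 and MET3 only the first was called, and in MRPS28, ATG1, the RPN9 tag set and YIL092W both were. On the mixed array PEX18 read 0.23, the RPN9 tag set -0.003 and RPC82 -0.11, from Pool A means of 1.42, 1.12 and 0.87. Adjusted over the list alone, the positive and negative counts became 1 and 4 for the nuclear pore, 0 and 5 for RNA polymerase, 0 and 4 for the peroxisome, 0 and 3 for the proteasome, 1 and 4 for amino acid biosynthesis and 2 and 21 for unnamed genes. They were as above for the other 9.

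The 2 tags of each strain gave separate readings of its difference. TFB3 read 7.01 and 6.09 and PFA5 4.42 and 5.17 in the first and second block. RPP1A read 0.59 and 5.50, TRS31 0.43 and 5.65, and SRP14 4.27 and 0.45. Of 10888 tags, 915 were called, 204 positive and 711 negative. These counts fell to 11 and 1 without Pool A replicate 1 and to 124 and 381 without replicate 2. Both tags of a strain were called positive in 31 strains, negative in 30 and in opposite directions in 8, while 777 strains had only 1 tag called. Both tags differed by at least 1 in 27 positive strains, 24 of them in the stretches, and in 13 negative strains. The lone Pool B self-self array, where no strain should differ, gave more strains with both tags called, in the same and in opposite directions. Across strains, which are not independent replicates, Pearson's correlation of the 2 differences was 0.23 and Spearman's 0.06. With Pool A replicates 1 to 3 in the lone place Pearson's correlation was 0.35, 0.05 and 0.27, and for the Pool B array it was 0.06.

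**Figure D3:**
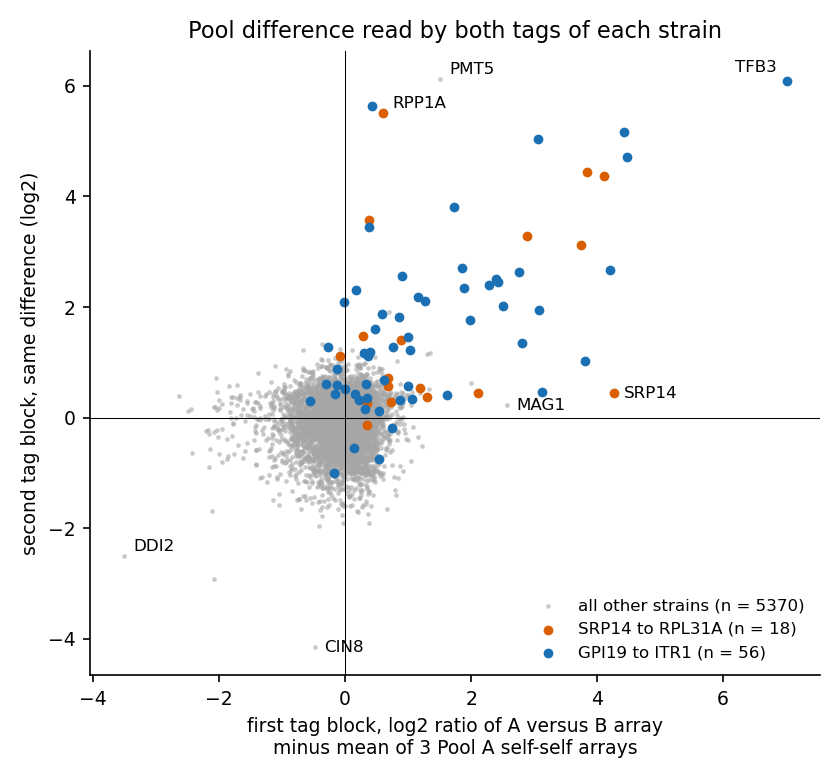
Log2 difference of each strain in the first (x axis) and second tag block (y axis), mixed array minus the mean of the 3 Pool A self-self arrays, with the 18 and 56 strains of the 2 chromosome IV stretches in colour. TFB3 lies at 7.01 and 6.09, RPP1A and SRP14 show the difference in 1 block, and most other strains lie within 1 log2 unit of 0 in both.

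The self-self arrays measured what the method returned where both channels held the same pool. On the Pool A arrays, 5258 of the 10888 tags departed from 0 by limma, 2803 upward and 2455 downward, of which 503 and 238 departed by at least 1. Centring sets the point from which up and down are counted, and without it 2870 tags departed from 0. MAG1 (2.79), TFB1 (1.49), PEX18 (1.42) and DOT6 (1.08) are named strains with such ratios. Correlations of tags between the Pool A arrays were 0.83 to 0.91, and those of the Pool B array with them 0.28 to 0.37 (0.14 to 0.31 in the first block and -0.03 to 0.26 in the second). The mixed array correlated with the Pool A arrays at 0.52 to 0.65 over both blocks, at 0.61 to 0.73 in the first and at 0.19 to 0.35 in the second. With the Pool B array it correlated at 0.39, 0.23 and 0.38 in the same order. The SD of the tags was 0.53, 0.57 and 0.63 on the Pool A arrays, 0.52 on the Pool B array and 0.66 on the mixed array. The share of tags at least 1 from 0 was 6.35%, 7.97% and 9.92% on the Pool A arrays, 4.49% on the Pool B array and 7.73% on the mixed array. For strains the shares were 1.51%, 2.20%, 3.10%, 0.643% and 3.55% in the same order. The skewness of the tags on the mixed array, 1.04, was above theirs (0.61, 0.81, 0.32 and 0.21).

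The lone Pool B self-self array, compared in the same way as the mixed array, gave more calls than the mixed array. Limma called 2310 tags, 859 positive and 1451 negative, and 1190 strains, 465 positive and 725 negative. No strain had both tags at 2 or beyond in the same direction in this comparison, against 14 positive and 2 negative strains on the mixed array. With both tags at 1 or beyond, the Pool B array gave 6 positive and 27 negative strains. Among the 74 strains of the stretches its median difference was 0.37. When each Pool A array took the lone place, limma called 0, 0 and 27 tags for replicates 1 to 3, with 1443, 221 and 339 tags at an unadjusted p under 0.05. Without replicate 1, the Pool B array also gave 0 calls, so the first of these zeros says little, whereas without replicates 2 and 3 it gave 1651 and 1546.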

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

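The tests of spot location, of unequal amounts and of block offsets described here were chosen only after the results were seen.

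A signal appeared at a pair of spots that the annotation leaves unnamed. The pair stands between the spots of GUK1 and NHX1, inside the longer chromosome IV stretch, and differed by 3.64 in the first block and 5.04 in the second. The second-block value was above the largest size of any unnamed spot within the blocks on a self-self array (4.44), and the first-block value was below it. Another unnamed pair, between APT2 and SSN2, differed by 2.91 and 0.31 and stayed below that level.

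The chromosome IV strains were weighed against the place of their spots on the array, because neighbouring genes have neighbouring spots. The stretches were defined from the first tag block alone, and the second block lies elsewhere in the spot numbering. In it, 58.1% of the 74 strains differed by at least 1, against 0.354% outside, which argues against spot location as the whole cause. Of the 27 strains with a second-tag difference of at least 2, 26 (96.3%) lay in the stretches, which is consistent with strains of these stretches having been added in unequal amounts. The labels do not list the 94 strains, so this remains a hypothesis, and the 23 uncalled strains of the stretches stay open between small dilution steps and no difference. Small positive values among them need not mark a dilution step. Pool B self-self minus the Pool A mean gave all 74 strains a median of 0.37. On the mixed array the unnamed block-end spots differed by medians of 0.36 and 0.43 in the 2 blocks.

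Outside the gene-named blocks, 321 unnamed spots were picked for high ratios on the mixed array and on every Pool A self-self array. Their median on the mixed array was 7.38 as deposited. Their medians on the Pool A self-self arrays were 6.86, 6.90 and 7.40. On the Pool B self-self array, which played no part in the choice, the median was -2.76. What these spots hold is not given in the sources used here.

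The second pattern is the 2310 tags called for the lone Pool B self-self array, where no strain should differ between channels. A trend along the spot numbers and different offsets of the blocks were examined as causes. After running medians were subtracted 3965 tags were called, and 3530 with the blocks centred separately. Both steps also raised the tag calls of the mixed array, so these counts cannot decide whether a trend or block offsets contributed. A Pool A array in the lone place gave calls for at most 0.248% of tags (27, replicate 3), so a difference in hybridisation batch or pool between the Pool B array and the others may account for the calls. With 1 such array, batch, pool and array are confounded, and the replicate 1 version had little power. The mixed array shares the batch of the Pool A arrays and still gave 318 negative strains, which this explanation leaves open.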

How the results depend on the processing

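The running median and the omission of tags resembling unnamed block-end spots were added after the data were seen, and all other alternatives were planned. The main counts were 204 positive and 711 negative tags, 84 and 318 strains, 2310 tags for the Pool B array and 5258 tags for the dye effect. Other counts that were recomputed stayed within 1.5 times these. The dye effect was recomputed only without centring, without each replicate and with all 4 self-self arrays, and the Pool B count not with the median of spots. Where no reason is stated, the cause was not tested.

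Without centring, 53 and 248 tags, 31 and 196 strains and 2870 dye-effect tags were called, and the median strain difference moved from -0.06 to -0.49. Separate centring of the blocks gave 398 positive tags and 3530 for the Pool B array. Scaling to one median absolute deviation gave 166 negative strains. Quantile normalization gave 548 positive tags, 179 negative strains and 3494 for the Pool B array, with 37.0% of strain calls positive against 20.9%. A required size of 1 left 106 and 388 tags, 47 and 57 strains and 1028 for the Pool B array, and adjusted p under 0.01 left 100 and 302, 52 and 118, and 1159, both fewer by construction. Without replicate 1, 2 or 3 of Pool A, ranges were 11 to 200 positive and 1 to 729 negative tags, 58 to 107 positive and 132 to 373 negative strains, and 0 to 1651 for the Pool B array. The lowest tag and Pool B counts came without replicate 1 (11, 1 and 0), and without replicate 2 there were 124 and 381 tags and 132 negative strains.

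With all 4 self-self arrays as reference, 45 and 27 tags, 27 and 6 strains and 2884 dye-effect tags were called, with 81.8% of strain calls positive. The Pool B array alone as reference gave 430 positive tags and 135 positive strains, of which 43 were among the main 84, and 99 of its 283 negative strains were among the main 318. The mixed array against 0 gave 779 and 1470 tags and 408 and 631 strains, 69 and 146 of them shared with the main calls. The running median gave 596 and 1304 tags, 345 and 659 strains and 3965 for the Pool B array. Spots tested singly gave 343 and 1244 called spots, and were not run for strains. The median size of positive strains was 1.46 with the larger tag in place of 1.13. With both tags called, 30 positive strains remained on chromosome IV in place of 61.

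Of the 51 positive strains in the stretches, 25 were kept with all 4 self-self arrays as reference, 30 without centring, 37 with the Pool B reference and at least 41 in every other setting. Of 86 named strains, 30 kept direction and call in every setting and 11 changed sign in some. With the Pool B reference, TFB1 (0.13), MIX23 (0.029), GLG2 (0.59), ILS1 (0.27), RPC82 (0.15), RAD10 (0.15), PEX18 (0.31) and an ATP11 tag set (0.31) turned positive, and a JIP4 tag set (-0.11) and LRS4 (-0.18) negative. Against 0, TFB1 (0.17), GLG2 (0.59), CDC23 (0.30) and PEX18 (0.23) turned positive. The strains that turned positive all had positive ratios on the Pool A self-self arrays, which the main reference subtracts.

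Requiring values on all 5 arrays changed nothing, as no value was missing. No paired analysis was possible because the groups share fewer than 2 replicate numbers. Signal over background is not in the deposited ratios, so which tags were too dim to read is unknown.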

Other observations

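The question of whether an unmoved tag had no signal was tested as planned before its result was seen, and the spot-run values were looked at only after the data were seen.

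In 10 strains of the stretches, 1 tag differed by at least 2 and the other by under 1, among them TRS31, RPP1A, SRP14, RXT3, HEH2, PUF6 and UTP6, chosen after their values were seen. One explanation is that the other tag gave no signal, in which case its ratios would resemble those of the unnamed spots that end each block. This held for 3 of the 10 (30%: TRS31, SRP14 and UTP6), against 9.05% of all named tags. The rule asked for values in the central range of those spots, and not on the mixed array alone. Block-end spots themselves can fall outside that range, so a tag without signal can fail the rule. The share therefore cannot decide, and the sample is too small. Among tags that failed, the differences of RXT3 (0.37), HEH2 (0.37), PUF6 (0.46) and RPL31A (0.45) lay near the block-end medians of 0.36 and 0.43. Those of RPP1A (0.59), VPS60 (0.91) and RPL27B (-0.02) lay further away. No biological explanation was tested.

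Runs of 5 neighbouring spots that repeat the same tag did not read alike. On Pool A self-self replicate 3, the median deviation from the tag's mean went from -0.29 at the first spot of the run to 0.30 at the last in the first block, and from -0.25 to 0.29 in the second. On the mixed array it went from -0.16 to 0.20 in the first block, and on the Pool B self-self array from -0.01 to 0.03. The median SD of the 6 spots of a tag was 0.08, 0.19 and 0.26 on the Pool A arrays, 0.05 on the Pool B array and 0.15 on the mixed array, beside 0.16 between the means of the 3 Pool A arrays.

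The unnamed spots that end each block differed by a median of 0.36 in the first and 0.43 in the second block after centring. As deposited, their medians on the mixed array (-0.17 and -0.10) lay within those of the Pool A arrays (-0.20 to -0.04 and -0.22 to -0.03). The positive difference thus came with the centring on named spots. The 985 named tags resembling them had a median difference of 0.36, against -0.09 for other tags, and 1 was called positive. A small positive difference can therefore arise in such a tag without unequal amounts.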
